A study of Lytechinus variegatus with 23 samples.

How the data were processed

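Whole Lytechinus variegatus embryos, untreated or exposed to alizarin red, were collected at 12, 18, 24 and 30 hours post fertilisation (hpf), with replicates A, B and C in each group and B and C alone for alizarin at 18 hpf, 23 libraries in all. Per the labels' protocols, RNA was extracted with TRIzol and mRNA libraries were made with a DNBSEQ kit. Per the submitters' processing notes, reads were aligned with STAR 2.7.1a. The genome build, the annotation, the counting tool, the dose and the time of exposure are not stated in the labels or file headers used here. The labels do not say whether replicates are separate cultures or crosses, so every p-value below measures only the spread between these libraries, which may be partly technical.

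The deposited table holds raw read counts per gene and library, per the file headers, and the values were whole numbers. It has 109578 lines because a gene is repeated for each protein match with the same counts. It was reduced to 27232 gene IDs with 0 conflicts between repeats, and 1 ID with unreadable counts was left out. Of the 27231 genes used, 26092 had at least 1 read. Columns were joined to samples by name, 0 columns of values were left unmapped, and 4 empty columns were dropped. The table pairs 21650 of the IDs with a symbol of the Strongylocentrotus purpuratus annotation, 18233 of them informative. Symbols are therefore names of the matched gene of another urchin, and 13076 IDs share a symbol with another ID, so that reads of near-identical copies (the Sm30, FoxQ2_1, histone and Cpa genes among them) may be split and their levels are uncertain. No positions are given, since no annotation of these IDs was used.

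Genes were kept with the edgeR filter filterByExpr (minimum count 10, 8 groups), which left 18419. Counts were scaled with TMM, and 1 model with 8 group means was fitted to all 23 libraries with the robust edgeR quasi-likelihood method (15 residual degrees of freedom, common biological coefficient of variation 0.423). The contrasts were alizarin minus control at each time, their mean, an F test of their differences, and successive control times. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and the SE is the absolute log2 fold change divided by the root of the F statistic. CPM values use the TMM library sizes. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The groups, contrasts, rule for named genes and the 21 gene lists as first written were fixed before the data were examined. The reported list tests use a later translation of their symbols.

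The lists were tested with limma's camera on voom values with a preset correlation of 0.01, adjusted over the 21 lists and 5 contrasts together, and again with the correlation estimated from the data. None of the 38 camera calls was kept with the estimated correlation, while fry, which asks whether a list's genes move one way and compares them with no others, called 13. In all 38 called tests the list's median, mean and test had the same sign, and in 22 of the other 67 they did not. The list symbols were translated to those of the annotation after the table was seen, and the lists as first written were run as an alternative. The ribosomal protein list was not among the 100 tests of that alternative. The lists cover skeletal matrix and PMC surface genes, PMC regulatory genes, skeletal patterning cues and receptors, ectoderm regulators, apical and neural, endoderm, pigment cell, blastocoelar and immune, muscle and coelom, and cilia genes. They also cover antioxidant genes, xenobiotic enzymes, ABC and organic ion transporters, heat shock, DNA damage, cell cycle, ribosomal protein, respiratory chain, calcium and proton handling, metal and iron, and collagen and matrix protease genes. Several genes stand in 2 lists.

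Named genes followed a rule. At each time it took the 8 largest rises and 8 largest falls among called genes with an informative name, a mean of at least 2 CPM in one group and no overlap between groups, where that many existed. For the mean effect it took 6 and 6 with the same sign at all 4 times, for the difference between times the 6 smallest p, and from each list up to 4 members with the smallest adjusted p. Catalase and the best expressed Sm50, Sm30, Msp130, Alx1, Vegf3 and Vegfr genes were always included. The text gives a part of these.

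Developmental age was estimated for each library by least squares of log2 CPM (prior count 2) on the piecewise linear profile of the control means, extrapolated by at most 6 h, on a grid of 0.05 h. It used 3937 genes changed at least 2-fold from 12 to 30 hpf that move one way over the 4 control means. Controls with the same replicate letter as the library were left out of its profile. The mean offset was tested by exact permutation of treatment labels within times. The predictions written for age-matched controls named the estimated age of the alizarin libraries. The script first used the collection hour less the offset (20.27 and 24.85 h), and the estimated age itself (20.78 and 24.4 h) was added after the results were seen.

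Each step was tested on simulated counts drawn from the real means and library sizes with 200 genes changed. Of genes changed 4-fold, 48%, 34%, 56% and 57% were recovered in the contrasts at 12, 18, 24 and 30 hpf, 90% in the mean effect and 7% in the test of differences between times. Of those changed 2-fold, 3%, 1%, 4% and 6% were recovered at the 4 times and 68% in the mean effect. False calls were 2, 1, 4, 0, 4 and 0 in these 6 contrasts. With at most 3 libraries per group, of 8194215 to 11730004 counts, many 2-fold differences at single times were thus not detectable. Depth was not varied in the simulation. Simulated delays of 0, 2 and 4 h gave offsets of -0.03, -1.97 and -3.44 h.

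Whether equal replicate letters pair libraries was checked by the correlation, across genes, of their deviations from the group means. At 30 hpf the 3 same-letter pairs had 0.503, 0.663 and 0.57, so the letters pair these libraries, by the data alone. At the other times the pairs of 1 letter within a time were not all above 0.1. Over all pairs of libraries from different groups the mean correlation was 0.121 for 77 same-letter pairs (those of 30 hpf included) and -0.061 for 154 others, so a shared source at the other times is not excluded. Single same-letter pairs across times reached 0.593 (control C at 18 hpf with alizarin C at 24 hpf). Different-letter pairs reached 0.639, 0.594 and 0.488, for controls A, B and C at 18 hpf with controls B, C and A at 24 hpf. A letter may thus not stand for the same source at every time. The letter blocks and the same-letter controls left out of the age profile would then pair unlike libraries. Alternatives were RLE, upper quartile and DESeq2 scaling and testing, no filter and a stricter filter, a 2-fold threshold, the replicate letter as a block over all libraries or within each time, fits of only the groups compared, leaving out the 18 hpf libraries, and leaving out each library in turn. A table of sample information in the deposit repeats the labels and was not used, and a reference gene table with no link to these IDs was not used.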

Results

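Whole embryos of the sea urchin Lytechinus variegatus were profiled by bulk mRNA sequencing, with and without alizarin red, a dye that binds calcium and is used to stain mineralised skeleton. Embryos were collected at 12, 18, 24 and 30 hours post fertilisation (hpf). Each group held 3 libraries, replicates A, B and C, except the alizarin group at 18 hpf, which held 2, B and C, giving 23 libraries. Total counts of control libraries A, B and C were 8978157, 8834924 and 8194215 at 12 hpf and 10038238, 9404030 and 10092561 at 18 hpf. They were 10896670, 11730004 and 11681877 at 24 hpf and 10836032, 11297779 and 10312291 at 30 hpf. Alizarin libraries had 9521720, 8468933 and 8978102 counts at 12 hpf and, for B and C, 9475030 and 9857376 at 18 hpf. At 24 hpf they had 9459626, 9688337 and 10418758 and at 30 hpf 10152050, 10403150 and 9881261. Between 19751 and 21768 genes had at least 1 count in a library. Levels below are mean CPM (counts relative to the scaled library total) ± SD over the 3 libraries of a group, 2 for alizarin at 18 hpf, and log2 fold changes are alizarin minus control with their standard error (SE).

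The series title places catalase, the enzyme that breaks down hydrogen peroxide, at the centre of the dye's action, so its transcript is given first. Catalase mRNA (Cat, L_var_26602) was lower in alizarin embryos on average over the 4 times, by a log2 fold change of -0.63 (SE 0.14, adjusted p = 0.0131 by the edgeR quasi-likelihood test). At 24 hpf the level was 200 ± 61 CPM in controls and 104 ± 14 CPM in alizarin embryos, a log2 fold change of -0.93 (SE 0.27). At 30 hpf it was 205 ± 26.3 CPM against 107 ± 14.7 CPM, again -0.93 (SE 0.27). At 12 hpf the levels were 80.5 ± 19.3 and 63.3 ± 17 CPM (-0.35, SE 0.27), and at 18 hpf 105 ± 26.7 and 84.7 ± 18.5 CPM (-0.31, SE 0.31). No single time passed the threshold across all genes: the edgeR adjusted p was 0.541, 0.98, 0.126 and 0.0643 at 12, 18, 24 and 30 hpf. With DESeq2 it was 0.0281 at 24 hpf and 0.0178 at 30 hpf. With the replicate letter as a block in a fit of the 30 hpf libraries alone, chosen after seeing the data, it was 0.000206 with a log2 fold change of -0.92. The fit of only the 30 hpf groups gave 0.0131 at -0.9. The difference between the times was not called (adjusted p = 0.673). Without alizarin replicate B of 18 hpf the mean effect was -0.58 with an adjusted p of 0.0612. Without control replicate A of 24 hpf the effect at 24 hpf was -1.16 with an adjusted p of 0.0497. The alizarin level at 24 hpf, 104 CPM, was near the 105 CPM of controls at 18 hpf. At 30 hpf, at 107 CPM, it was below the 200 CPM of controls at 24 hpf. Alizarin libraries were placed at younger ages than controls (below), and no comparison of catalase with age-matched controls is given here. These values are of the transcript, and enzyme activity was not measured.

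Catalase belongs to a list of 68 genes of antioxidant defence and reactive oxygen production. For the mean effect over the times 2 of them rose, 4 fell and 62 did not pass; adjusted over the list alone, 2 rose and 5 fell. Nox4 (L_var_09400), an NADPH oxidase that makes hydrogen peroxide, rose at 24 hpf from 5.09 ± 1.27 to 18.4 ± 1.48 CPM (log2 fold change 1.85, SE 0.33, adjusted p = 0.00727) and at 30 hpf from 1.98 ± 0.572 to 9.86 ± 1.1 CPM (2.32, SE 0.35, adjusted p = 0.000986). The Nox4 call at 24 hpf was lost without control replicate B (adjusted p = 0.0782). A superoxide dismutase gene (Sod, L_var_06369) fell by 1.94 on the log2 scale in the mean effect (SE 0.42, adjusted p = 0.0118). The glutathione peroxidase gene Gpx1 (L_var_26059), of an enzyme that removes peroxides, rose by 2.33 (SE 0.60, adjusted p = 0.0291). The Gpx1 call was lost in 5 of 23 fits that left out 1 library (highest adjusted p 0.108, without alizarin replicate B of 18 hpf). The list as a whole was called lower by camera only at 12 hpf (adjusted p = 0.0348), and the adjusted p was 0.469 with an estimated correlation and 0.0564 with the replicate letter as a block. At 12 hpf none of its members passed over all genes or adjusted over the list alone in edgeR, 9 did at an unadjusted p under 0.05 (1 higher, 8 lower), and DESeq2 called 2 lower. Camera gave an adjusted p of 0.801 at 30 hpf and 0.104 for the mean effect.

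**Figure D1:**
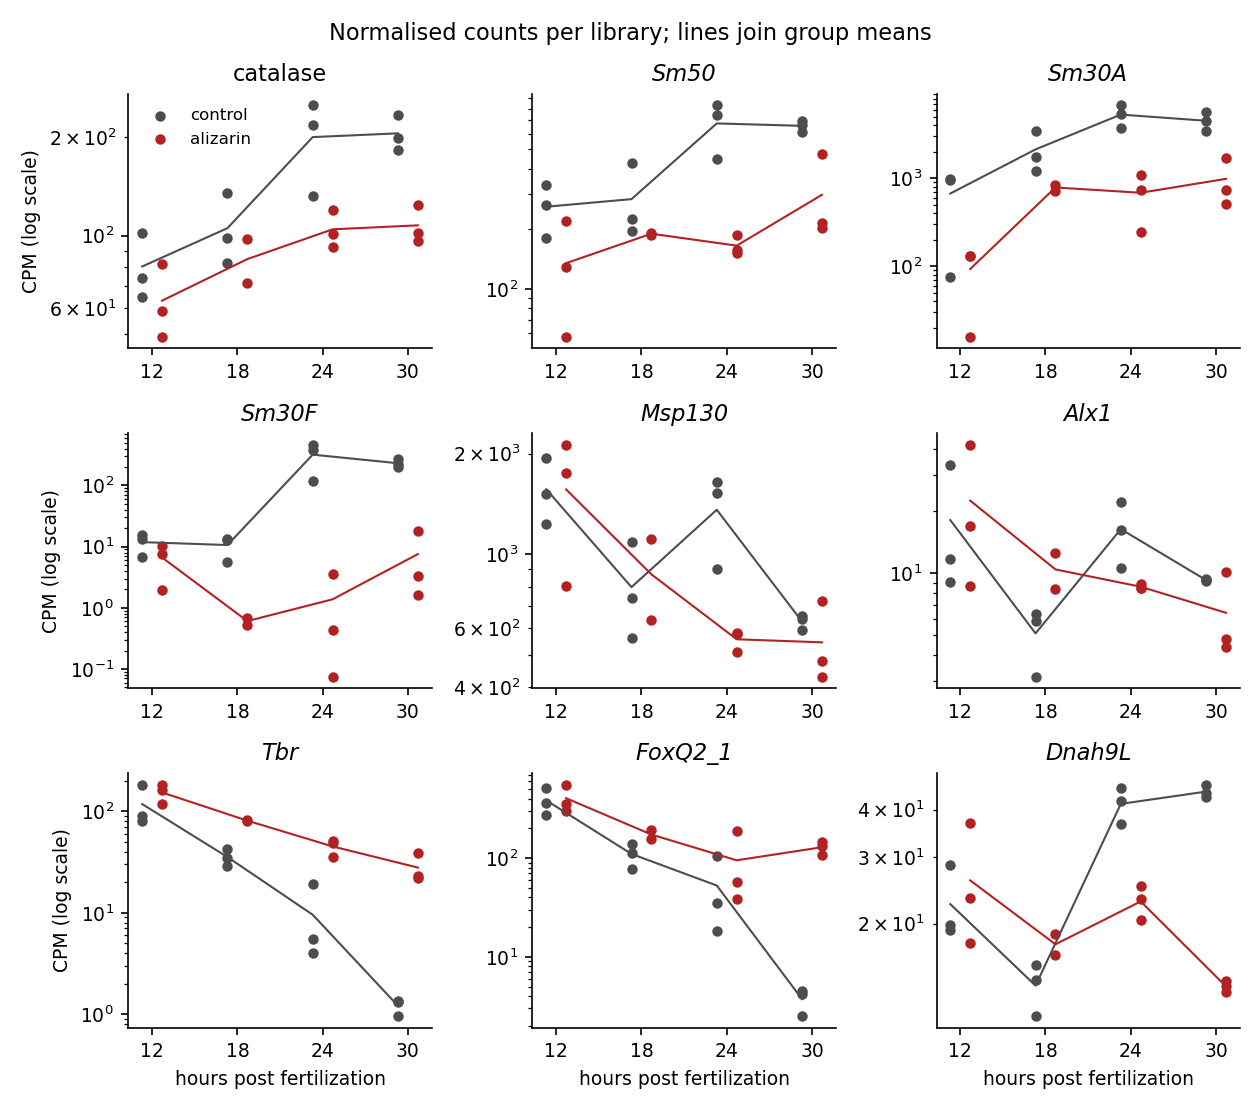
CPM on a log axis against hours post fertilisation for 9 genes, with 1 point per library (control grey, alizarin red, offset sideways) and lines joining the group means. Catalase was at 205 CPM in controls and 107 CPM in alizarin embryos at 30 hpf, Sm30F at 318 against 1.38 CPM at 24 hpf, and Tbr at 1.21 against 27.9 CPM at 30 hpf.

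At 12 hpf, before the larva has a skeleton, few single genes differed: 5 rose and 13 fell of 18419 tested. Acsf2_3 (L_var_00267), named after an acyl-CoA synthetase, fell from 15.8 ± 3.54 to 2.53 ± 0.907 CPM (log2 fold change -2.64, SE 0.29, adjusted p = 0.000259). Pcsk2 (L_var_13346), named after a proprotein convertase that processes neuropeptides, rose from 0.76 ± 0.347 to 5.56 ± 1.51 CPM (2.82, SE 0.40, adjusted p = 0.00541), and its call was lost without control replicate C (adjusted p = 0.0572). Acsf2_3 was the only one of the 14 named genes called at 12 hpf that passed in every fit leaving out 1 library.

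The list tests with the smallest adjusted p at 12 hpf were those of protein synthesis and respiration, and the control libraries were themselves uneven there. Cytosolic ribosomal proteins took 2.54% of the counts in control replicate A and 8.56% and 8.65% in B and C, against 2.14%, 2.34% and 4.12% in alizarin A, B and C. Camera called the 81 ribosomal protein genes lower (median log2 fold change -1.66, adjusted p = 4.24e-30, but adjusted p = 0.375 with an estimated correlation). The ribosomal protein list as first written was not tested. Camera also called the 59 respiratory chain genes lower (-0.78, 1.26e-14, but adjusted p = 0.378 with an estimated correlation). In edgeR none of either list passed over all genes; adjusted over the list alone 71 ribosomal and 20 respiratory genes fell. At an unadjusted p under 0.05 these counts were 71 and 31, and DESeq2 called 40 and 12 lower. Cilia genes were called higher (median 0.40, adjusted p = 8.48e-07, but adjusted p = 0.375 with an estimated correlation). None of 61 passed over all genes, 4 rose adjusted over the list alone, 14 were higher at an unadjusted p under 0.05, and DESeq2 called 6. Skeletal matrix and primary mesenchyme cell (PMC) surface genes were called lower (median -0.33, adjusted p = 2.61e-04, but adjusted p = 0.469 with an estimated correlation). The median log2 CPM of the list was 3.56 in control A, 5.05 in B and 5.39 in C, and 3.95, 2.6 and 3.6 in alizarin A, B and C, so control A lay within the alizarin range. None of 44 passed over all genes, 7 were lower adjusted over the list alone, 12 at an unadjusted p under 0.05 and 5 in DESeq2. Of 204 xenobiotic enzymes 2 fell and 202 did not pass, and adjusted over the list alone 1 rose and 10 fell (camera adjusted p = 8.67e-04, but adjusted p = 0.375 with an estimated correlation). DNA damage and apoptosis genes were called higher (median 0.51, adjusted p = 0.00143, but adjusted p = 0.378 with an estimated correlation). None of 46 passed over all genes or the list alone, 5 were higher and 3 lower at an unadjusted p under 0.05, and DESeq2 called 1 lower.

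The count at 12 hpf rested on single libraries: it was 911 without control replicate A, 1 without control C, 33 without alizarin A, 7 without alizarin B and 106 without alizarin C. DESeq2 called 698 genes, and a fit of only the 12 hpf groups called 0, so that Acsf2_3 and Pcsk2 also missed the threshold (both adjusted p 0.519). A replicate block gave 97 calls over all times and 65 within each time. The 2 groups did not overlap for 17 of the 18 called genes and for 13.29% of all genes, where chance gives 10%.

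At 18 hpf no single gene passed the test, with 2 alizarin libraries against 3 controls. The edgeR test called 0 genes, 1045 had an unadjusted p under 0.05, and DESeq2 called 51, of which 9 rose and 42 fell. Groups did not overlap for 21.35% of genes, where chance gives 20%. Camera called 4 lists. Skeletal matrix and PMC surface genes were lower (median log2 fold change -0.40, adjusted p = 0.00111, but adjusted p = 0.496 with an estimated correlation), with 5 of 44 lower at an unadjusted p under 0.05. Cilia genes were higher (median 0.19, adjusted p = 0.00121, but adjusted p = 0.469 with an estimated correlation), with 3 of 61 higher at an unadjusted p under 0.05. Xenobiotic enzymes were lower (median -0.29, adjusted p = 0.00148, but adjusted p = 0.378 with an estimated correlation), with 6 of 204 higher and 21 lower at an unadjusted p under 0.05. Muscle and coelom genes were lower (median -0.21, adjusted p = 0.0314, but adjusted p = 0.521 with an estimated correlation and 0.0564 with the replicate letter as a block), with 1 of 26 higher and 3 lower at an unadjusted p under 0.05. No member of these 4 lists passed over all genes in edgeR, and adjusted over the list alone 1 muscle and coelom gene fell. DESeq2 called 1 xenobiotic and 1 muscle and coelom gene lower and none of the skeletal or cilia genes.

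**Figure D2:**
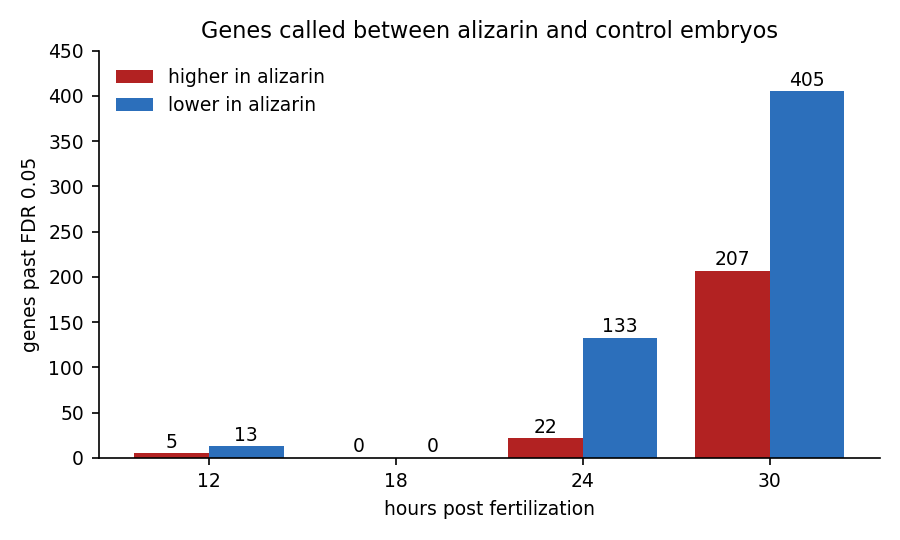
Number of genes called higher and lower in alizarin embryos (vertical axis, edgeR, adjusted p under 0.05) at each collection time in hours post fertilisation (horizontal axis). Counts were 5 and 13 at 12 hpf, 0 and 0 at 18 hpf, 22 up of 155 called at 24 hpf, and 207 and 405 at 30 hpf.

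At 24 hpf, when control embryos expressed their biomineralisation genes strongly, several of these transcripts were lower in alizarin embryos. Sm30F (L_var_26911), a spicule matrix protein gene, fell from 318 ± 178 to 1.38 ± 1.95 CPM (log2 fold change -7.80, SE 1.10, adjusted p = 0.00158). Msp130r2 (L_var_22350), related to a PMC surface glycoprotein, fell from 665 ± 234 to 88 ± 7.02 CPM (-2.92, SE 0.39, adjusted p = 0.000534), and C-lectin/PMC1 (L_var_26903) from 67 ± 29.3 to 3.41 ± 0.802 CPM (-4.30, SE 0.61, adjusted p = 0.00118). Sm50 (L_var_27181), another spicule matrix gene, fell from 675 ± 200 to 165 ± 19.5 CPM (-2.04, SE 0.43, adjusted p = 0.0271). The Sm50 call held without control replicate A and was lost in the other 5 fits that left out 1 library, with the highest adjusted p, 0.148, without alizarin replicate A. The carbonic anhydrase gene Cara7LA (L_var_04705), of an enzyme class that supplies carbonate, fell from 109 ± 10.3 to 10.9 ± 9.06 CPM (adjusted p = 0.0112, and 0.0996 without alizarin replicate A). Of the 44 skeletal matrix and PMC surface genes 9 fell and 35 did not pass, and adjusted over the list alone 25 fell. Camera called the list lower (median -1.47, adjusted p = 1.23e-18, but adjusted p = 0.155 with an estimated correlation). Sm30A (L_var_26913), the most abundant Sm30 gene, was at 5272 ± 1509 and 683 ± 415 CPM (-2.95, adjusted p = 0.1), and Msp130 (L_var_22165) at 1358 ± 400 and 556 ± 40.7 CPM (-1.29, adjusted p = 0.103).

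Among regulators and signals of the skeletogenic cells, none of the named genes fell past the test at 24 hpf, and Tbr rose. Alx1 (L_var_16422), a transcription factor needed for PMC specification, was at 16.3 ± 5.83 CPM in controls and 8.6 ± 0.247 CPM in alizarin embryos (-0.93, adjusted p = 0.505). The patterning signal Vegf3 (L_var_00379) was at 5.91 ± 0.159 and 7.27 ± 2.54 CPM (0.30, adjusted p = 0.784), and its receptor Vegfr10 (L_var_00558) at 21.2 and 34.5 CPM (0.71, adjusted p = 0.39). Tbr (L_var_02106), a T-box regulator expressed in the PMC lineage, rose from 9.55 ± 8.29 to 45.1 ± 8.7 CPM (2.24, SE 0.44, adjusted p = 0.0182). The Tbr call held without control C or alizarin C and was lost without control A, control B, alizarin A or alizarin B, with the highest adjusted p, 0.138, without control B. It was 0.0988 in a fit of only the 24 hpf groups.

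Some genes of the muscle, cilia, endoderm and pigment cell lists also passed at 24 hpf. MyoR2 (L_var_25173), of a muscle lineage transcription factor family, fell from 24.7 ± 5.7 to 0.721 ± 0.532 CPM (-5.02, SE 0.85, adjusted p = 0.00727). Of 26 muscle and coelom genes 2 fell and 24 did not pass (adjusted over the list alone 5 fell; camera adjusted p = 8.67e-04, but adjusted p = 0.375 with an estimated correlation). Of 61 cilia genes 2 fell and 59 did not pass, and adjusted over the list alone 15 fell (camera adjusted p = 6.42e-07, but adjusted p = 0.375 with an estimated correlation). Of 56 endoderm genes 2 fell and 54 did not pass; adjusted over the list alone 1 rose and 4 fell (adjusted p = 0.0098, but adjusted p = 0.348 with an estimated correlation). Of 48 pigment cell genes 1 rose, 1 fell and 46 did not pass, and the same numbers were called adjusted over the list alone (median -0.58, adjusted p = 0.00286, but adjusted p = 0.375 with an estimated correlation). The one that rose was Pks2 (L_var_00620), a polyketide synthase gene, from 14.2 ± 5.95 to 108 ± 28.9 CPM (2.92, SE 0.50, adjusted p = 0.00609). Its place in this list rests on its symbol, and whole embryos do not show which cells express it. Of 70 collagen and matrix protease genes 1 rose, 4 fell and 65 did not pass, and adjusted over the list alone 3 rose and 9 fell (adjusted p = 0.0333, but adjusted p = 0.521 with an estimated correlation). Within it Timp3 (L_var_06196), a metalloproteinase inhibitor, rose from 2.42 ± 1.7 to 21.6 ± 6.19 CPM (3.16, SE 0.50, adjusted p = 0.00336). Ribosomal protein genes were called lower by camera (median -0.55, adjusted p = 1.46e-05, but adjusted p = 0.631 with an estimated correlation). The edgeR test called 0 of 81 over all genes or the list alone, 6 were lower at an unadjusted p under 0.05 and DESeq2 called 0. The libraries were uneven: these genes took 10.48% and 11.29% of counts in alizarin A and B but 17.25% in C, within the 14.86% to 19.66% of the controls. On the second principal component alizarin C lay at 43.8 and A and B at -61.2 and -62.1. Respiratory chain genes were called lower (median -0.13, adjusted p = 0.0209, but adjusted p = 0.719 with an estimated correlation), with 1 of 59 lower over all genes and 2 adjusted over the list alone.

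In all 155 genes passed at 24 hpf, 22 of them (14.2%) up and the rest down. The share up was 21.6% with upper quartile scaling (25 up, 91 down). Without control A 14 of 167 were up, and without control B 3 of 45. The groups did not overlap for any of the 155, against 17.38% of all genes and 10% by chance. The count was 45 without control B, 67 without control C, 41 without alizarin A, 65 without alizarin B and 93 without alizarin C. DESeq2 called 505 genes, and a replicate block within each time called 304.

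At 30 hpf some skeletal genes were again lower, and single regulatory genes of different lists were higher. Tbr rose from 1.21 ± 0.223 to 27.9 ± 9.35 CPM (log2 fold change 4.51, SE 0.52, adjusted p = 7.72e-05). FoxQ2_1 (L_var_17029), of a regulator family of the animal pole, rose from 3.73 ± 1.07 to 129 ± 19.8 CPM (5.11, SE 0.65, adjusted p = 0.000239). FoxY (L_var_09987), named with the coelom genes, rose from 1.33 ± 0.553 to 20.2 ± 10.5 CPM (3.92, SE 0.60, adjusted p = 0.00107). Not (L_var_19596), an ectoderm regulator, rose from 35.5 ± 1.13 to 145 ± 13.1 CPM (2.03, SE 0.39, adjusted p = 0.00724). These 4 calls were kept in every fit that left out 1 library of 30 hpf.

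Among skeletal matrix and PMC surface genes 9 of 44 fell at 30 hpf and 35 did not pass, and adjusted over the list alone 1 rose and 20 fell. Sm30F fell from 230 ± 34.2 to 7.55 ± 8.88 CPM (-4.96, SE 0.96, adjusted p = 0.00859, and 0.0586 without alizarin replicate C), and Cara7LA from 150 ± 35.8 to 19.9 ± 9.72 CPM (-2.92, adjusted p = 0.0113). The Cara7LA call was lost without alizarin B or alizarin C, with the higher adjusted p, 0.077, without C. Camera called the list lower (median -1.14, adjusted p = 1.94e-10, but adjusted p = 0.24 with an estimated correlation). Of 20 PMC regulatory genes Tbr rose and 19 did not pass, over all genes and adjusted over the list alone (camera adjusted p = 0.478). Of 29 skeletal patterning cues and receptors 1 fell, Pax2 (adjusted p = 0.0102, lost without alizarin A at 0.0531 and also without alizarin C), and 28 did not pass, and adjusted over the list alone 1 fell (adjusted p = 0.703). Of 58 calcium and proton handling genes 4 fell and 54 did not pass, and adjusted over the list alone 1 rose and 11 fell (adjusted p = 0.0702). One was the sodium/calcium exchanger gene Slc8a3 (L_var_17752), from 184 ± 13.8 to 64.3 ± 1.3 CPM (-1.52, SE 0.28, adjusted p = 0.006).

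Of 61 motile cilia genes 14 fell at 30 hpf and 47 did not pass, and adjusted over the list alone 19 fell. The axonemal dynein heavy chain gene Dnah9 (L_var_17364) fell from 412 ± 56.7 to 94.2 ± 21.9 CPM (-2.13, SE 0.36, adjusted p = 0.00227). Its relative Dnah9L (L_var_15732) fell from 44.6 ± 1.76 to 13.7 ± 0.424 CPM (-1.71, SE 0.25, adjusted p = 0.000758). Hydin_2 (L_var_03155), whose product is part of the ciliary central apparatus, fell from 49.4 ± 3.92 to 10.7 ± 1.86 CPM. Camera called the list lower (median -0.37, adjusted p = 3.18e-07, but adjusted p = 0.348 with an estimated correlation).

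In the gut and mesoderm lists at 30 hpf, 1 of 56 endoderm genes rose, 4 fell and 51 did not pass, and adjusted over the list alone 1 rose and 7 fell (camera adjusted p = 0.00648, but adjusted p = 0.348 with an estimated correlation). A carboxypeptidase A gene (Cpa, L_var_04535), of a digestive enzyme, fell from 56.3 ± 13.7 to 5.55 ± 1.75 CPM (-3.34, SE 0.61, adjusted p = 0.00506). Of 26 muscle and coelom genes 2 rose, 2 fell and 22 did not pass, and adjusted over the list alone 2 rose and 5 fell (adjusted p = 0.0269, but adjusted p = 0.469 with an estimated correlation). SoxE (L_var_17157) fell from 130 ± 6.82 to 29 ± 2.05 CPM (-2.16, SE 0.38, adjusted p = 0.00385), and the myosin light chain kinase gene Mlcka (L_var_02450) from 174 ± 15.2 to 54.6 ± 8.17 CPM. Of 70 collagen and matrix protease genes 3 rose, 5 fell and 62 did not pass, and adjusted over the list alone 3 rose and 11 fell (adjusted p = 0.0159, but adjusted p = 0.469 with an estimated correlation). Of 52 blastocoelar and immune genes 2 fell and 50 did not pass, and adjusted over the list alone 3 fell (adjusted p = 0.338). Of 39 apical and neural genes 2 rose, both named FoxQ2_1, 1 fell and 36 did not pass; adjusted over the list alone 3 rose and 3 fell (adjusted p = 0.118). Of 21 ectoderm regulators 2 rose, among them Not, and 19 did not pass, and adjusted over the list alone 3 rose and 1 fell (adjusted p = 0.609).

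Transport and housekeeping lists were mixed at 30 hpf. Of 100 ABC and organic ion transporters 6 fell and 94 did not pass, and adjusted over the list alone 1 rose and 11 fell (camera adjusted p = 3.49e-06, but adjusted p = 0.24 with an estimated correlation). Ribosomal protein genes were called higher by camera, with a positive log2 fold change in 80 of 81 and a median of 0.63 (adjusted p = 3.21e-05, but adjusted p = 0.649 with an estimated correlation). None of the 81 passed in edgeR over all genes or the list alone, none had an unadjusted p under 0.05, and DESeq2 called 0. Ribosomal proteins took 26.04% of counts in alizarin replicate A, 20.74% in B and 20.25% in C, and 15.1% to 18.66% in the controls. Of 65 heat shock and unfolded protein response genes 1 rose, Hsp90L, and 64 did not pass, over all genes and adjusted over the list alone (adjusted p = 0.00516, but adjusted p = 0.433 with an estimated correlation). Of 89 cell cycle and DNA replication genes 7 rose, 4 fell and 78 did not pass, and adjusted over the list alone 12 rose and 8 fell (adjusted p = 0.478). Of 37 metal binding and iron genes 1 fell, Cp, and 36 did not pass, and adjusted over the list alone 1 fell (adjusted p = 0.969). The Hsp90L call held without alizarin A and was lost in the other 5 fits that left out 1 library (highest adjusted p 0.109, without control A), and the Cp call was lost without alizarin B (0.0527) or alizarin C.

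In all 612 genes passed at 30 hpf, 207 up and 405 down, and with upper quartile scaling, which moved the median of all genes by 0.106, 269 up and 317 down. The groups did not overlap for 607 of the 612 and for 32.23% of all genes, where chance gives 10%. Each library left out lowered the count, to 180, 245 and 218 without control A, B and C and to 252, 197 and 170 without alizarin A, B and C. DESeq2 called 1190 genes and the fit of only the 30 hpf groups 2001. The replicate block in the 30 hpf libraries alone, chosen after seeing the data, called 5286, with Sm30F then at -5.34 and an adjusted p of 0.078. Genes called at both 24 and 30 hpf, which share no library, numbered 87, of which 12 were up and 75 down at both times and 0 went in opposite directions. Independent lists of these sizes would share 0.247 up and 2.92 down.

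**Figure D3:**
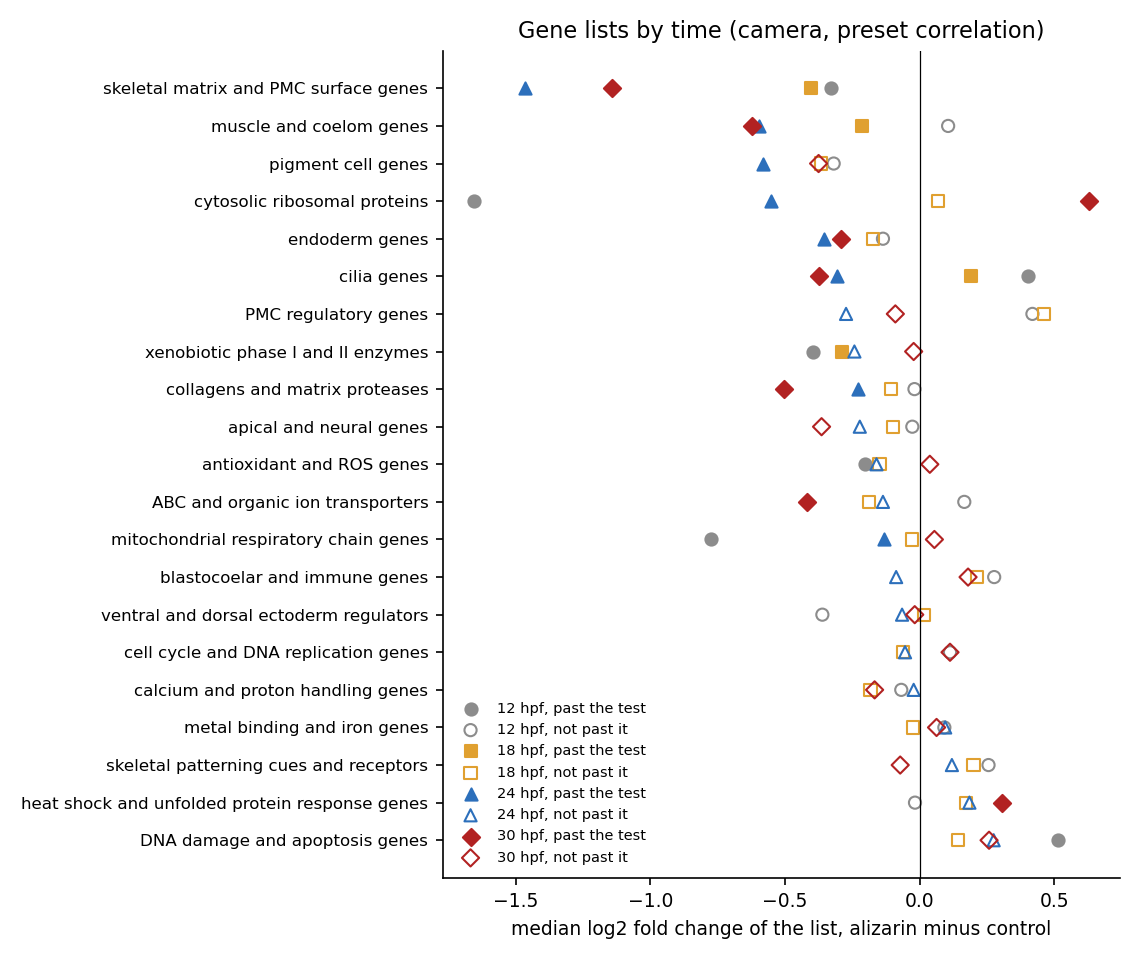
Median log2 fold change (horizontal axis, alizarin minus control) of each of the 21 gene lists, with a circle, square, triangle and diamond for 12, 18, 24 and 30 hpf, filled where the camera adjusted p was under 0.05. The skeletal matrix and PMC surface list lies at -0.33, -0.40, -1.47 and -1.14 at the 4 times, and cytosolic ribosomal proteins at -1.66 at 12 hpf and 0.63 at 30 hpf.

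Averaged over the 4 times, the skeletal list had the smallest camera p of the lists. Of the 44 skeletal matrix and PMC surface genes 19 fell and 25 did not pass, and adjusted over the list alone 24 fell (median log2 fold change -0.86, camera adjusted p = 1.39e-17, but adjusted p = 0.187 with an estimated correlation). Sm30F fell by 4.42 (SE 0.53, adjusted p = 0.000121), Cara7LA by 2.55 (SE 0.32, adjusted p = 0.000148) and Msp130r2 by 1.40 (SE 0.19, adjusted p = 0.000262). Clect_76 (L_var_22169), a C-type lectin gene, had a mean log2 fold change of -5.33 (SE 0.49, adjusted p = 3.47e-06). Sm30A and Sm50, of which Sm30A was not called at 24 hpf, had mean effects of -2.36 (SE 0.42, adjusted p = 0.00312) and -1.18 (SE 0.22, adjusted p = 0.00383). Tbr rose by 2.08 (SE 0.23, adjusted p = 3.01e-05), Timp3 by 2.05 (SE 0.25) and Pks2 by 1.98 (SE 0.25), while Pks1 (L_var_23510), the polyketide synthase gene of larval pigment cells, changed by -1.05 (SE 0.21, adjusted p = 0.00643). All 10 of these calls were kept in every fit that left out 1 library.

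Some enzymes of detoxification also fell in the mean effect. Of 204 xenobiotic phase I and II enzymes 4 rose, 16 fell and 184 did not pass, and adjusted over the list alone 5 rose and 24 fell (camera adjusted p = 4.76e-04, but adjusted p = 0.375 with an estimated correlation). The glutathione S-transferase gene Gst11 (L_var_26389) had a mean log2 fold change of -1.61 (SE 0.25, adjusted p = 0.00118). The cytochrome P450 gene Cyp3L10 (L_var_15527) rose by 4.06 (SE 0.80, adjusted p = 0.00634). Of 48 pigment cell genes 1 rose, 6 fell and 41 did not pass, and adjusted over the list alone 1 rose and 7 fell (adjusted p = 0.00151, but adjusted p = 0.375 with an estimated correlation). Of 46 DNA damage and apoptosis genes 4 rose and 42 did not pass, and 11 rose adjusted over the list alone (camera adjusted p = 0.00334, but adjusted p = 0.469 with an estimated correlation). Camera also called ABC and organic ion transporters (adjusted p = 0.0141), muscle and coelom genes (0.0237), endoderm genes (0.0247) and collagens and matrix proteases (0.0437) lower and heat shock genes higher (0.0159). With an estimated correlation the adjusted p of the endoderm list was 0.375 and that of collagens 0.536, and the other 3 had 0.469. Over all genes 1 transporter rose and 3 fell, 1 muscle and coelom gene rose and 3 fell, 2 endoderm genes fell, 3 collagen and protease genes rose and 12 fell, and 1 heat shock gene rose. Adjusted over the list alone the transporters had 1 up and 5 down, muscle and coelom genes 2 and 8, collagens and proteases 6 and 14, and heat shock genes 1 up. The endoderm list had 0 in edgeR adjusted over the list alone, with 2 up and 8 down at an unadjusted p under 0.05 and 5 down in DESeq2. Collagens also missed the threshold with the replicate block (0.0564) and with RLE size factors (0.0507). Respiratory chain genes (median -0.20, adjusted p = 5.67e-05, but adjusted p = 0.626 with an estimated correlation) included 3 that fell and 56 that did not pass, with 3 lower adjusted over the list alone. Ribosomal protein genes had a median of -0.36 (adjusted p = 2.61e-04, but adjusted p = 0.717 with an estimated correlation) with opposite signs at 12 and 30 hpf. The edgeR test called 0 of 81 over all genes or the list alone, 5 were lower at an unadjusted p under 0.05, and DESeq2 called 2 lower. The lists as first written were fixed before the table was seen, and their use as an alternative was chosen after. With them camera called 17 of 100 tests, ribosomal proteins not being tested. Among these calls were the skeletal and the cilia list at each time and in the mean effect. Camera called none of the tests of xenobiotic, muscle and coelom, endoderm, collagen or heat shock genes. It also did not call the mean effect of DNA damage genes (adjusted p = 0.0855) or transporters (0.0511), the transporters at 30 hpf (0.0542) or the respiratory chain at 24 hpf (0.495). In all 928 genes passed for the mean effect, 388 up and 540 down, and with upper quartile scaling the excess turned, with 478 up and 460 down. That count was 1416 without alizarin replicate A of 12 hpf and 385 without alizarin replicate B of 18 hpf, and DESeq2 called 1709. Without the 12 hpf libraries, left out after seeing the data, it was 1797.

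The effect of alizarin differed between the times for 93 genes by the edgeR F test on the differences of the 4 contrasts. C10orf112L (L_var_10185) gave the smallest adjusted p, 0.000264. At 12 hpf its log2 fold change was 0.75 (SE 0.50, adjusted p = 0.467). At 24 hpf it fell from 7.04 ± 2.28 to 0.4 ± 0.235 CPM (log2 fold change -4.11, SE 0.47) and at 30 hpf from 136 ± 15.1 to 3.44 ± 1.27 CPM (-5.29, SE 0.43). Pcsk2 was higher in alizarin embryos at 12 hpf (2.82). At 30 hpf it was at 10.7 ± 1.89 against 21.5 ± 2.43 CPM in controls (-1.0, SE 0.33) without passing (adjusted p = 0.111). Its adjusted p for the difference was 0.00541. Dnhd1L (L_var_20551), named after a dynein heavy chain domain, was at 12.5 ± 1.9 CPM in alizarin embryos and 45.6 ± 6.07 CPM in controls at 30 hpf. Rej5 (L_var_17573), of the receptor for egg jelly family, was there at 9.31 ± 1.69 against 50.3 ± 3.31 CPM, and Klhl12 (L_var_07203) at 9.53 ± 2.08 against 45 ± 0.758 CPM. All of these, with Nox4, passed the test of a difference in every fit that left out 1 library. Without the 12 hpf libraries, left out after seeing the data, C10orf112L had an adjusted p of 0.201, Klhl12 of 0.683 and Pcsk2 of 0.851, and the count was 67. The count was 355 without control A, 48 without control B and 35 without control C of 12 hpf, 38 and 44 without control A and B of 18 hpf, 48 and 53 without control B and C of 24 hpf, and 18, 31 and 28 without control A, B and C of 30 hpf. Among alizarin libraries it was 141 without B of 12 hpf, 48 and 41 without B and C of 18 hpf, 54 and 52 without A and B of 24 hpf, and 38, 33 and 26 without A, B and C of 30 hpf. It was 42 without the 18 hpf libraries and 725 in DESeq2.

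Control embryos alone show the developmental course on which these differences lie. From 12 to 18 hpf 2750 genes changed, 1558 up and 1192 down, from 18 to 24 hpf 918, 741 up and 177 down, and from 24 to 30 hpf 171, 132 up and 39 down. Skeletal matrix and PMC surface genes rose in 8 of 44 cases from 18 to 24 hpf, with Sm30F up by 4.91 on the log2 scale (adjusted p = 0.0043) and Msp130r2 by 2.51 (adjusted p = 0.000461). In the same step 16 of 61 cilia genes rose, Dnah9 by 2.13 (adjusted p = 0.00108), and 5 of 26 muscle and coelom genes, MyoR2 by 6.23 (adjusted p = 0.000613). Nox4 changed by -2.39 from 18 to 24 hpf (adjusted p = 0.000188). From 24 to 30 hpf Tbr changed by -2.96 (adjusted p = 0.00427), FoxQ2_1 (L_var_17029) by -3.82 (adjusted p = 0.00302) and FoxY by -4.29 (adjusted p = 0.000836), while the Cpa gene L_var_04535 rose by 6.1 (adjusted p = 0.000129). Catalase was higher at 24 than at 18 hpf by 0.92 without passing (adjusted p = 0.0539). The count from 12 to 18 hpf was 1776 without control replicate A of 18 hpf and 981 in a fit of only these groups. From 18 to 24 hpf it was 386 and 392 without A and B of 18 hpf and 444 and 564 without B and C of 24 hpf, and 1609 in DESeq2. From 24 to 30 hpf it was 84 and 45 without B and C of 24 hpf and 77, 106 and 71 without A, B and C of 30 hpf, 507 in DESeq2 and 575 in a fit of only these groups.

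Set against that course, alizarin libraries were placed at a younger age than controls on average over the times, with the larger differences at 24 and 30 hpf. The age of each library was estimated from 3937 genes that move in one direction in controls. Controls and alizarin embryos were placed at 12.52 ± 0.69 and 12.2 ± 0.35 h at 12 hpf, 18.47 ± 1.51 and 16.62 ± 1.52 h at 18 hpf, 24.52 ± 1.63 and 20.78 ± 0.18 h at 24 hpf, and 29.55 ± 0.82 and 24.4 ± 2.04 h at 30 hpf. The differences were -0.32, -1.84, -3.73 and -5.15 h, with exact permutation p of 0.5, 0.3, 0.1 and 0.1, where 0.1 is the smallest that 3 against 3 or 3 against 2 libraries allow. Their mean was -2.76 h (exact permutation test within times, two-sided, p = 0.00055, 80000 arrangements). All alizarin libraries of 24 and 30 hpf were placed below all controls of the same hour. Leaving out 1 library gave -2.49 to -3.2 h with exact p from 0.00025 to 0.00954, and leaving out the 12 hpf libraries, chosen after seeing the data, -3.57 h (exact p = 0.00075).

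**Figure D4:**
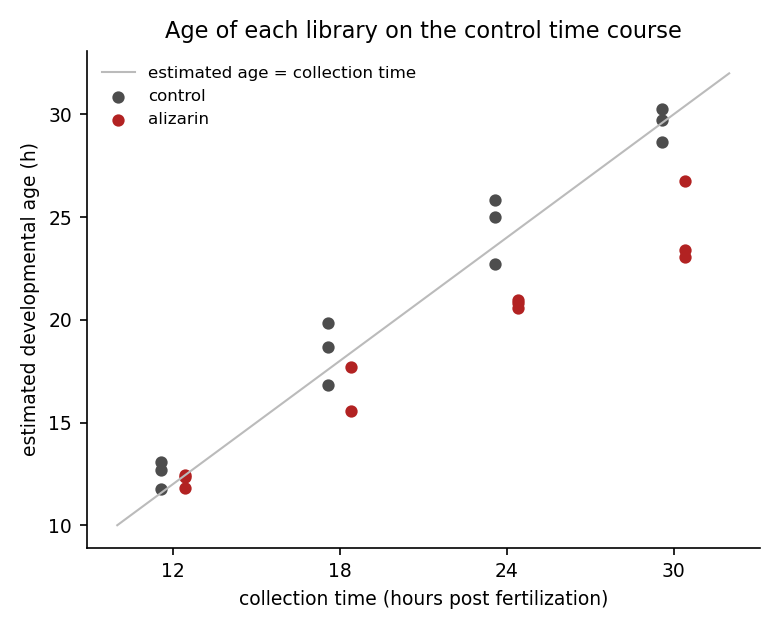
Estimated developmental age in hours (vertical axis) against collection time in hours post fertilisation (horizontal axis), 1 point per library, control grey and alizarin red, with a line where both are equal. Alizarin libraries at 24 hpf lie at 20.6 to 20.95 h, and controls of that time at 22.7 to 25.85 h.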

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

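The tests of scaling, of the 24 hpf calls against age-matched controls, of controls at the estimated age itself and of the spread of ribosomal protein genes between controls were chosen only after the results were seen, and the remaining tests before. The effect of alizarin differed between the times for 93 genes by the edgeR F test. Of 100 splits of the libraries within times 4, the real one included, called as many, with 386 as the highest of the others. That share is under 5% only by a margin within the sampling error of 100 drawn splits. The splits exchange treatment labels within each time and so also break up the mean effect. They therefore cannot decide whether the differences between the times are chance. Why a split gave 386 calls was not tested. The 6 genes named for this test were chosen as those with its smallest p. C10orf112L (adjusted p = 0.000264) had log2 fold changes of 0.75 at 12 hpf (not called), -4.11 at 24 hpf and -5.29 at 30 hpf. Pcsk2 (0.00541) had 2.82 at 12 hpf and -1.0 at 30 hpf (not called). Without the 12 hpf libraries C10orf112L had an adjusted p of 0.201, Klhl12 of 0.683 and Pcsk2 of 0.851. Dnhd1L (0.00939), Rej5 (0.00968) and Klhl12 (0.00968) were lower in alizarin embryos at 30 hpf, by -1.87, -2.43 and -2.24, and Nox4 (0.00968) was higher, by 2.32.

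The lower skeletal matrix and PMC surface genes at 24 and 30 hpf could reflect embryos at an earlier stage, the scaling, or a change in the skeletogenic cells. Against control means interpolated to the collection hour less the estimated offset (20.27 and 24.85 h), the median log2 fold change of the list was -0.94 at 24 hpf (-1.47 at the same hour) and -1.1 at 30 hpf (-1.14). Camera gave adjusted p of 3.31e-13 and 2.18e-12, and unadjusted p of 0.0115 and 0.0097 with an estimated correlation. The same-hour camera values with an estimated correlation, 0.155 and 0.24, were adjusted over 105 tests. The unadjusted p therefore do not show a stronger fall against age-matched controls. With controls at the estimated age itself (20.78 and 24.4 h) the median was -0.98 and -1.17 (camera adjusted p = 7.85e-16 and 7.19e-12, unadjusted p of 0.00626 and 0.0121 with an estimated correlation). These medians argue against a delay of the estimated size as the whole cause. At 24 hpf this rests on a straight line between controls of 18 and 24 hpf. The list's median log2 CPM was 4.58, 4.94 and 4.48 in alizarin A, B and C of 24 hpf. It was 4.59, 4.8 and 5.27 in controls A, B and C of 18 hpf. A longer delay of these genes than of the whole embryo is thus not covered. In edgeR 0 single members were called at 24 hpf against either set of controls, and 11 were at 30 hpf. Over 4 scalings and both times the median was at most -0.94, which argues against scaling. What stays open is a longer delay of these genes, or a change in the number of skeletogenic cells or in their transcription. Whole embryos do not separate these, so an effect of alizarin on these cells beyond delay is a hypothesis.

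The many genes called at 24 and 30 hpf may in part be those of younger embryos. At 24 hpf only 3 of the 155 calls, 1.9% (95% exact interval 0.4 to 5.6%), were kept in the same direction against controls at the hour less the offset, and 4 (2.6%) against controls at the estimated age, as the median size of their log2 fold changes went from 2.37 to 0.79 and 0.96. At 30 hpf 315 of 612 were kept, 51.5% (47.4 to 55.5%), an interval that spans the bound of 1 in 2 set beforehand. With controls at the estimated age 280 were kept (45.8%, 41.8 to 49.8%). The median size of the 612 log2 fold changes went from 1.82 to 1.27 and 1.24. In all 1082 and 1033 genes differed from these 2 sets of controls. Both sets rest mostly on the 24 hpf libraries (weights 0.858 and 0.933), so other differences between collections may enter these counts. They therefore cannot decide whether delay is the whole difference at 30 hpf. Delay and other effects cannot be told apart for this set. Of the 251 genes called both at 30 hpf and in controls from 18 to 24 hpf, with no library shared, 100% went the other way than in development, and 54 of 61 (88.5%) did so for 24 hpf against controls from 12 to 18 hpf. Delay gives a reversed direction for genes that still change after the estimated ages, 24.4 h at 30 hpf and 20.78 h at 24 hpf. The control steps used end before these ages, at 24 and 18 hpf. A reversal of these steps therefore cannot decide on a delay of the estimated size. Delay may itself be an effect of the dye. The few calls kept at 24 hpf cannot decide on delay either. The matched age was fitted to the same libraries without removing the called genes, which by itself draws them toward these controls. Only 4% of simulated 2-fold changes were recovered in the same-hour contrast at 24 hpf, so remaining effects of 0.79 or 0.96 could be missed. The 10 splits at each time are too few for a share under 0.05 (612 and 155 genes against a highest other of 0, 1 split each).

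The lower ribosomal protein genes at 12 hpf may come from differences between libraries rather than from alizarin. The list's median log2 CPM spanned 2.42 over the 3 control libraries (7.72 in A, 10.14 in B, 10.05 in C), more than the difference of the group means of -1.47. With the labels of control A and alizarin C exchanged, the 12 hpf effect correlated across genes with the later effect by 0.211. With the labels as given it was 0.377, which goes against an exchange. Of the 10 splits of the 12 hpf libraries 4, the real one included, called at least the 18 genes of the real one. The highest, 859, came from control A with alizarin A and B against the rest. That is the grouping of the exchanged labels, so this count goes with an exchange, and the 2 results together do not decide it. Scaling is argued against, since the median was at most -1.1 over 4 scalings. Embryo batch, RNA handling, exchanged labels and a response to alizarin in some libraries stay open, and the cause of the 859 calls was not tested.

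The other counts of called genes were compared with other splits of their libraries. For the mean effect the real split, with 928 genes, was the only 1 of 100 with as many, and the highest other was 179. That share is under 0.05, but 100 drawn splits bound chance without excluding it. For controls from 12 to 18, 18 to 24 and 24 to 30 hpf the 10 splits are too few for a share under 0.05, with 2750, 918 and 171 genes in the real split and 0 in the highest other.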

How the results depend on the processing

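The block in the 30 hpf libraries alone and the fits without the 12 hpf libraries were chosen after seeing the data. So was the run of the lists as first written, although these lists themselves were fixed before. All other alternatives were chosen before. None of the alternatives reversed a called result. The number of genes called depended on the tool and on single libraries more than directions did: of 174 named calls 83 passed in every fit leaving out 1 library, 91 were lost in at least 1, and 0 changed sign. Over 2427 such named results 2029 stayed on their side of the threshold, 371 were lost and 27 gained. The cause was not tested, except that fits with fewer libraries have fewer degrees of freedom.

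At 12 hpf, with 18 genes in the reported fit, the count was 9 with RLE, 8 with upper quartile, 43 with the stricter filter and 698 with DESeq2. Fitting only the groups compared gave 0 genes at 12 hpf, 2001 at 30 hpf, 981 for controls from 12 to 18 hpf and 575 from 24 to 30 hpf. DESeq2 called 51 genes at 18 hpf, 505 at 24 hpf, 1190 at 30 hpf, 1709 for the mean effect, 725 for differences between times, 1609 for controls from 18 to 24 hpf and 507 from 24 to 30 hpf. The 2-fold threshold left 502 for the mean effect. Without the 18 hpf libraries 42 genes differed between times. Without the 12 hpf libraries 1797 had a mean effect.

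As a replicate block the letter gave 97 genes at 12 hpf over all libraries and 65 within each time, 304 at 24 hpf within each time, and 5286 in the 30 hpf libraries alone. Same-letter correlations were 0.126, -0.022 and 0.128 at 12 hpf, 0.082 and 0.112 at 18 hpf and -0.242, 0.192 and -0.052 at 24 hpf, so not every pair passed 0.1 there, which does not exclude a shared source. Of 105 list tests the block ended 3 calls, given with those lists, and of 192 named results the block over all libraries ended 3 and gained 5, the block within each time ended 17 and gained 2, and of 61 at 30 hpf the block in those libraries ended 4 and gained 2. The block changed no other count by over 1.5 times.

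Leaving out 1 library gave 1 (control C) to 911 (control A) genes at 12 hpf, 41 (alizarin A) to 167 (control A) at 24 hpf, 170 (alizarin C) to 252 (alizarin A) at 30 hpf, 385 to 1416 for the mean effect (alizarin B of 18 hpf and A of 12 hpf) and 18 to 355 for differences between times (control A of 30 hpf and of 12 hpf). Control counts ranged from 1776 to 2887 (A of 18 hpf, C of 12 hpf), 386 to 863 (A and C of 18 hpf) and 45 to 156 (C and A of 24 hpf).

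Catalase passed at 24 hpf with DESeq2 (-0.94), and at 30 hpf with the block in these libraries alone (-0.92), DESeq2 (-0.94) and only the groups compared (-0.9); its mean effect of -0.63 did not reach 2-fold. Leaving out 1 library gave -0.58 (alizarin C) to -0.14 (control B) at 12 hpf and -0.6 (alizarin C) to -0.09 (control C) at 18 hpf. The range was -1.16 (control A) to -0.74 (control C) at 24 hpf and -0.7 (alizarin C of 18 hpf) to -0.58 (control B of 12 hpf) for the mean.

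Of 38 list calls 0 were kept with the estimated correlation, fry called 13, and the lists as first written 17 of 100, of which 15 were shared. The block within each time was not run for control times, nor the 2-fold threshold for the F test. With these libraries most simulated 2-fold changes at 1 time were not recovered.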

Other observations

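The test of on and off genes was chosen only after these genes had been seen. At 30 hpf histone genes of the early embryo were among the largest rises, with the highest levels in alizarin replicate A. ClvhH2b (L_var_27130), named after a cleavage-stage histone, was at 196 CPM in alizarin A, 15.3 in B and 38.4 in C, and at 0.715 to 1.31 CPM in controls. ClvhH1 (L_var_17578) was at 178, 6.16 and 19.9 CPM against 0.21 to 0.871, and EhH3_57 (L_var_03117) at 221, 7.18 and 22.7 CPM against 0.105 to 0.653. The symbol EhH3_57 is shared by 19 IDs, of which only this one is given. The EhH3_57 and ClvhH2b calls were kept in all 6 fits that left out 1 library. The ClvhH1 call held without alizarin B or C and was lost in the other 4 (highest adjusted p 0.101, without control A). With the replicate letter as a block in the 30 hpf libraries alone, chosen after seeing the data, ClvhH2b was called (log2 fold change 6.07, adjusted p = 0.0383). There EhH3_57 (7.14, 7.51 without the block, adjusted p = 0.0778), ClvhH1 (7.11 without and 6.74 with it, 0.0848) and ClvhH2a (5.96 and 4.5, 0.258) were not. Of the 8 named rises at 30 hpf 5 had an SD above the mean in alizarin embryos, and all 5 were highest among the 30 hpf libraries in replicate A, which also had the highest share of ribosomal protein counts (26.04%) and the lowest TMM factor (0.616).

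Cell cycle genes moved both ways at 30 hpf. The geminin-like GmnnL (L_var_25271), of an inhibitor of replication licensing, rose from 5.81 ± 1.38 to 20.8 ± 8.42 CPM (log2 fold change 1.84, adjusted p = 0.00663). Both CycA genes (L_var_00785 and L_var_00647) rose by 1.94 and 1.76 and Cdt1 (L_var_04452) by 1.29, while Ncapg (L_var_20191) changed by -1.04 and the kinesin gene Kif2CL (L_var_19177) by -0.81. For the mean effect Pcna (L_var_25876), the replication clamp, changed by -0.68 (adjusted p = 0.0187). CycA, Cdt1, Ncapg, Kif2CL and Pcna lie outside the rule for named genes and were chosen after their values were seen.

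Some genes were on in some libraries of a group and off in others, which may follow parentage if libraries with the same replicate letter come from the same cross. This was a hypothesis formed on these data. The 13 genes chosen were above 3 CPM in some libraries and below 0.15 CPM in others of the same group, in several groups. Their highest level was above 10 CPM, and few libraries lay between the bounds. Same-letter pairs agreed in 0.706 and different-letter pairs in 0.647 of states, a difference of 0.059 (p = 0.0027 in 10000 shuffles of letters within groups, a permutation test). Of 13 pairs in full agreement 12 shared a letter. Among all pairs from different groups 77 share a letter and 154 do not. Pairs within a group never share a letter and differ through the choice of these genes, which lowers the 0.647. The shuffles within groups keep this feature. The labels do not say what a letter stands for, so a shared cross, day or batch stays open.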
